A study of Mus musculus with 3 samples.

How the data were processed

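The series holds 3 libraries of ribosomal RNA-depleted total RNA from the cytosolic fraction of mouse bone marrow-derived macrophages stimulated with lipid A (100 ng/ml, 60 min). The labels give 1 group, number the libraries as biological replicates 1 to 3 and list a separate biosample for each, with a shared donor entry that names the mouse strain. Nothing else says that the cultures came from separate mice, so p-values measure the spread between these samples, which may be technical.

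For each library there was a gene table, a transcript table and a second transcript table. Per the file headers, the first pair of tables gives the expected count, TPM and FPKM per gene and per transcript, in columns named as RSEM writes them. FPKM is taken as fragment counts scaled by transcript length and depth, and TPM as scaled over all features of a file. The column names do not define either. Per the file headers, the percent of a gene's TPM in each transcript is given in the transcript table. The second deposited transcript table gives an estimated count and TPM per transcript, in columns named as kallisto writes them, and is called kallisto's here. The build is mm10 with GENCODE M21 per the deposited description files. Aligner and quantifier versions are not given in the sources used here. Whether the counting used strand is not given in the sources used here either, so antisense and overlapping genes are uncertain. All 55536 annotated gene IDs in the tables matched the GENCODE M21 annotation of GRCm38, the build called mm10, from which names, biotypes and coordinates were taken.

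TPM divides by effective length, which is far below the annotated length for short RNAs. RNAs of about the length of a sequenced fragment therefore take a larger share of TPM than of counts, and every other gene's TPM is lower for it. For that reason levels were also compared with the library's own median gene.

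Rows that are not annotated genes (ERCC spike-ins, phiX and 26248 numbered features) were left out of library sizes and tests. They held 0.260, 0.0933 and 0.0577% of the counts, nearly all phiX. Counts assigned to annotated genes were 63944236, 71989793 and 69305836 in replicates 1, 2 and 3. Intervals on shares are 95% Wilson intervals, and a count of 0 was taken to allow up to 3 counts.

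Before the data were examined, 29 gene lists were fixed, 2 of them by name pattern (ribosomal protein genes and replication-dependent histones). They cover immediate early genes, cytokines and chemokines, NF-kB inhibitors and subunits, MAPK phosphatases, type I interferons, interferon-stimulated genes, Toll-like receptor 4 signalling, late inflammatory genes, alternative activation, inflammasome, macrophage and lysosome genes, nuclear-retained RNAs, a list named cytoplasmic noncoding RNAs that also holds the mainly nuclear Rpph1 and Rmrp, mitochondrial messages, cell cycle, mRNA decay, glycolysis and housekeeping genes. They also cover markers of neutrophils, T and NK cells, B cells, dendritic cells, erythroid cells, mast cells and basophils, and stroma and endothelium. Il12b and Ctsd stand in more than 1 list, as do Gapdh, Pgk1 and Rplp0. Of a symbol with several gene IDs the most abundant was used. The genes named in the text were chosen by a rule fixed at the same time. It takes the 4 members of each list with the highest mean TPM (8 for cytokines and immediate early genes), any type I interferon or other cell type member of at least 1 TPM, the 10 highest nuclear-encoded protein-coding genes, the 5 highest noncoding genes, and the 8 genes of at least 10 TPM with the highest BCV. Genes named outside the rule are marked as such.

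With 1 group, no comparison between conditions was possible, and none is made. Expressed genes are those with a mean of at least 1 TPM. Levels were tested with limma 3.58.1 (R 4.3.3) in an intercept-only fit of log2(TPM + 0.1) minus the library's median over the tested protein-coding genes of at least 1 TPM, using treat with a band of 1 on the log2 scale, a trended prior and Benjamini-Hochberg adjustment at 0.05. Differences on the log2(TPM + 0.1) scale understate those of low genes. A list's median TPM was placed among 10000 random lists of the same size, leaving out members under 1 TPM from both. A total of 4 differences between lists were taken within each library over all members and tested with an exact sign-flip permutation test, whose smallest 2-sided p with 3 libraries is 0.25. Expected counts were rounded to whole numbers, scaled by TMM and filtered with filterByExpr in edgeR 4.0.16, which left 13026 genes for the tagwise BCV (intercept-only design) and for chi-square tests of the counts against effective library sizes. List medians of BCV were placed among 10000 lists matched in 20 bins of abundance. The rest was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

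Alternatives were kallisto's values, TPM rescaled over nuclear-encoded protein-coding genes, a pseudocount of 1, FPKM, no filter on low values, a minimum mean of 5 TPM, the size factors and gene-wise dispersions of DESeq2 1.42.0, and leaving out each library. Rescaling kallisto's TPM in the same way was added after the data were seen.

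The procedures were tested on simulated data. For the levels, 9123 simulated genes included 200 genes 4-fold above and 200 genes 4-fold below the typical gene. The limma test recovered 100% of each and called 0 of the others. The others were drawn well inside the 2-fold band, so error rates for genes near its edge were not measured. For counting error, 13026 genes with 200 raised 2-fold in 1 library gave 95.5% recovered and 9 false calls. The BCV placed a simulated list of 200 genes with 3 times the variability at percentile 100, but with 3 libraries it understated the size. Where the BCV of other genes was spread with a prior like the real one, the median of the 200 genes was 0.294 against a simulated 0.463, and that of the other genes 0.202 against 0.165. Where all other genes shared a BCV of 0.15, shrinkage was stronger and the 200 genes came out at 0.174 against a simulated 0.45. BCV values are therefore read as ranks and not as sizes. Only lists of 200 independently varying genes were simulated. How often a smaller, co-regulated or ordinary list reaches a high percentile was not measured.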

Results

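Total RNA depleted of ribosomal RNA was sequenced from the cytosolic fraction of bone marrow-derived macrophages of C57BL/6J mice. The cells had been stimulated with lipid A, the part of bacterial lipopolysaccharide that activates Toll-like receptor 4, at 100 ng/ml for 60 min. All 3 libraries belonged to this 1 group and are called replicates 1, 2 and 3 after their labels, and each was made from 1 µg of RNA. No unstimulated cells and no nuclear fraction were analysed here, so levels are described within the stimulated cytosol and no induction was measured. The files held 64110863, 72057046 and 69345880 expected counts for replicates 1, 2 and 3. A count of 0 in these libraries allows up to 3 counts, which is 0.0469, 0.0417 and 0.0433 CPM. Intervals and floors cover counting error only.

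Among messenger RNAs, the ferritin light and heavy chain genes Ftl1 and Fth1, whose products store iron, led at 8244 ± 827 and 8115 ± 1252 TPM (length-scaled transcript abundance; mean ± SD, n = 3). They were followed by Lyz2, which encodes lysozyme, at 5032 ± 2089 TPM, and Psap, which encodes the precursor of the saposins, at 4251 ± 819 TPM. The lysosomal protease genes Ctsd and Ctsb stood at 3388 ± 764 and 2503 ± 1004 TPM. Selenop, Gpnmb, Tmsb4x and Actb completed the 10 highest nuclear-encoded protein-coding genes, between 1966 ± 304 TPM for Actb and 2480 ± 781 TPM for Selenop. Of the 55536 annotated genes, 9711 had a mean of at least 1 TPM, among them 9123 protein-coding genes, 167 processed pseudogenes and 68 long intergenic noncoding RNAs. Per library, 10061, 9197 and 9617 genes reached 1 TPM, and 9102 did so in every library. Raising the minimum mean to 5 TPM left 5850 genes.

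All 23 tested members of the macrophage list lay above the library's median protein-coding gene by more than 2-fold, with Lyz2, Ctsd, Apoe (apolipoprotein E, 1723 ± 323 TPM) and Lgals3 (galectin 3, 1476 ± 252 TPM) at the top. The list's median was 190 ± 61.5 TPM, above each of 10000 random lists of the same size (percentile 100). The remaining member, the chemokine receptor gene Cx3cr1, lay under 1 TPM and was named after its value was seen. All 22 lysosome genes were likewise above the median gene, led by Psap, Ctsd, Ctsb and the cathepsin S gene Ctss (816 ± 304 TPM), with a list median of 257 ± 83.0 TPM. The test behind these counts was limma's one-sample moderated test against a 2-fold band around the library's own median of 9.08, 5.76 or 6.86 TPM, adjusted by the Benjamini-Hochberg method. Across 9123 protein-coding genes it called 2403 above and 2236 below, and 4484 were not called. Counts above and below are calls of this test, and a gene not called can still lie more than 2-fold from the median gene. Without a filter on low values the counts were 4986 above and 5463 below among 14388 genes, and only 200 of the 2236 genes stayed below. With kallisto's TPM 1427 genes were below, 806 of them shared.

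**Figure D1:**
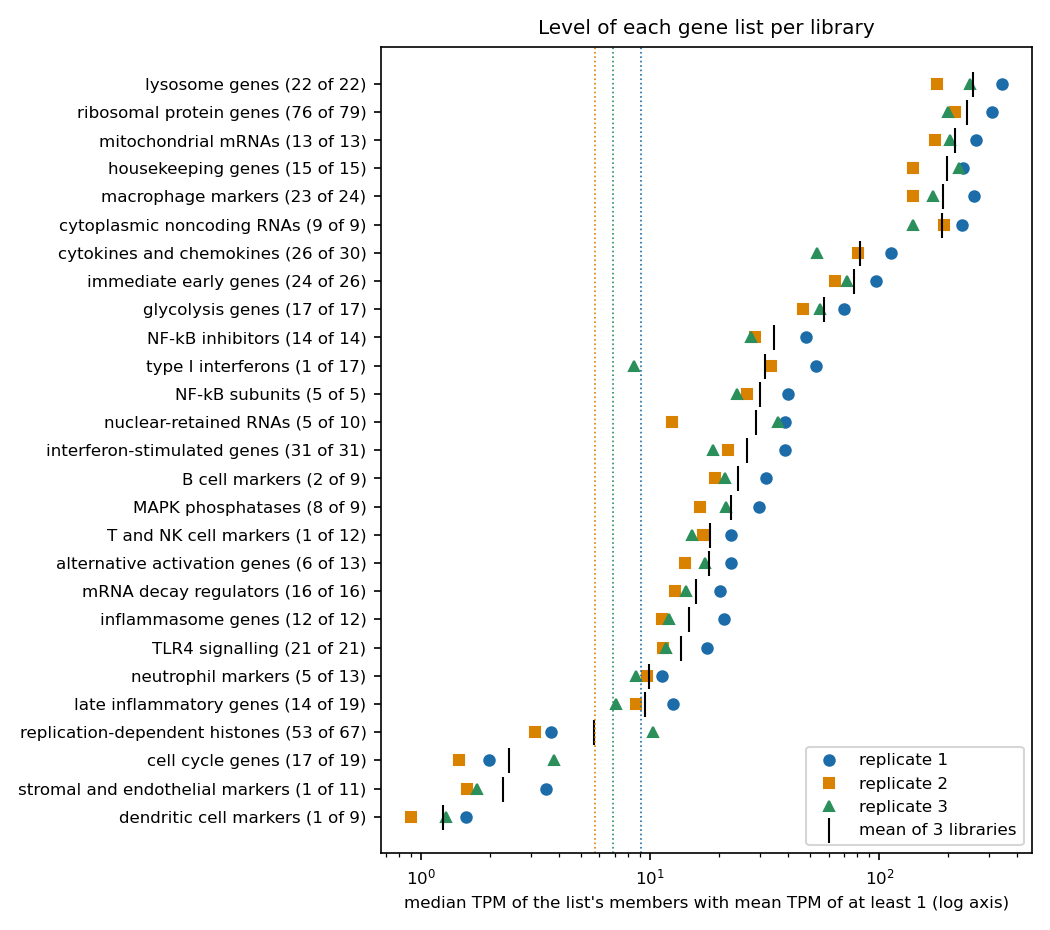
Median TPM of each fixed gene list (log axis) in replicates 1, 2 and 3, over the members with a mean of at least 1 TPM, whose number is given in brackets, with the mean of the 3 libraries as a vertical tick; the dotted lines mark each library's median tested protein-coding gene (9.08, 5.76 and 6.86 TPM). Lysosome genes had the highest mean median, 257 TPM, and the expressed dendritic cell marker the lowest, 1.25 TPM.

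Early inflammatory transcripts were among the most abundant messages in the cytosol. Tnf, which encodes the cytokine TNF, reached 1641 ± 701 TPM (n = 3), 7.75 ± 0.17 (SE) above the median gene on the log2 scale (limma adjusted p = 2.6e-07). The gene (ENSMUSG00000024401.14) lies on chromosome 17 at 35199381 to 35202007 of GRCm38. The chemokine genes Ccl4, Cxcl2, Ccl3 and Ccl2 followed at 1050 ± 523, 970 ± 324, 927 ± 412 and 514 ± 193 TPM. The interleukin-1 genes Il1b and Il1a stood at 818 ± 239 and 449 ± 119 TPM, and Tnfsf9, which encodes the ligand of 4-1BB, at 465 ± 162 TPM. Of the 26 cytokine and chemokine genes tested, 16 were above the median gene, 3 below (Il27, Cxcl3 and Ccl22, named after their values were seen) and 7 were not called. The other 4 members, Il12a, Csf3, Cxcl9 and Cxcl11, had a mean under 1 TPM and were also named after their values were seen. The list's median was 82.4 ± 29.6 TPM over the members above 1 TPM, at percentile 100.

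Immediate early genes, which are transcribed without new protein synthesis, were abundant too. Junb, a subunit of the AP-1 transcription factor, was highest at 438 ± 54.2 TPM, followed by Rgs1 (a regulator of G protein signalling, 367 ± 125), Atf3 (293 ± 128) and Klf6 (272 ± 64.8 TPM). Egr1, Plk2, Ier3 and Fos stood at 193 ± 34.1, 176 ± 54.9, 162 ± 55.5 and 134 ± 9.25 TPM. Among 24 tested members 19 were above the median gene, 2 below (Klf4 and Plk3, named after their values were seen) and 3 were not called. The list's median was 77.6 ± 17.2 TPM, at percentile 100.

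Regulators of the same pathways were also present. In the list named NF-kB inhibitors, Nfkbia, Tnfaip3 and Nfkbiz reached 774 ± 148, 413 ± 116 and 349 ± 103 TPM, while Nfkbib stood at 47.6 ± 10.02 TPM. Whether each member of the list acts as an inhibitor was not tested. Of its 14 genes 9 were above the median gene and 5 were not called. All 5 subunit genes were above it, led by Rel (42.8 ± 15.5 TPM), Rela (35.5 ± 8.29), Nfkb2 (30.1 ± 8.64) and Nfkb1 (27.6 ± 8.03 TPM). Among phosphatases of MAP kinases, 5 of 8 tested genes were above and 1 below, with Dusp1 at 438 ± 89.1, Dusp2 at 82.8 ± 35.2, Dusp5 at 51.2 ± 3.64 and Dusp4 at 27.7 ± 10.1 TPM. Zfp36, whose protein destabilises AU-rich messages such as that of Tnf, stood at 729 ± 169 TPM, and its relatives Zfp36l1 and Zfp36l2 at 160 ± 32.8 and 42.7 ± 10.7 TPM. With Zc3h12c (35.7 ± 15.8 TPM), 8 of 16 regulators of mRNA decay were above the median gene and 1 was below. The medians of the inhibitor, subunit, phosphatase and mRNA decay lists were 34.6 ± 11.3, 30.1 ± 8.64, 22.5 ± 6.80 and 15.8 ± 3.82 TPM. The median gene of the inhibitor list exceeded the median subunit gene by 0.19 ± 0.07 on the log2(TPM + 0.1) scale. The sign was the same in 3 of 3 libraries (exact sign-flip permutation test, 2-sided p = 0.25, the smallest that 3 libraries allow).

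**Figure D2:**
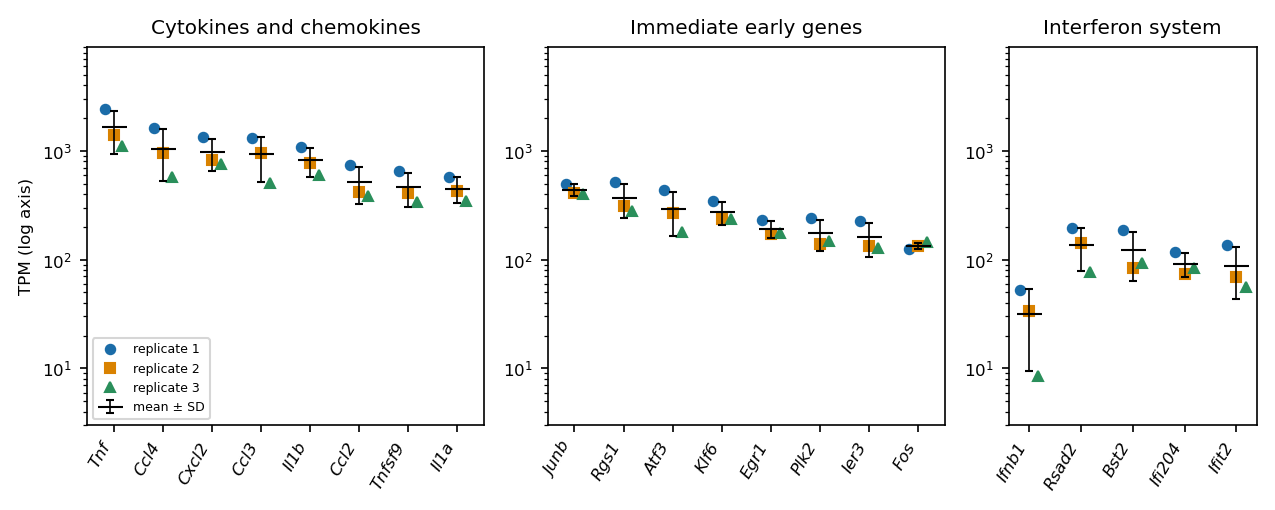
TPM (log axis) of the named cytokine, immediate early and interferon-system genes in replicates 1, 2 and 3, with bars for mean ± SD (n = 3). Tnf has the highest mean at 1641 TPM, and Ifnb1 ranges from 8.47 TPM in replicate 3 to 52.7 TPM in replicate 1.

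Of the type I interferon genes, Ifnb1 alone exceeded 1 TPM. It stood at 52.7, 33.5 and 8.47 TPM in replicates 1, 2 and 3 (31.6 ± 22.2), from 2581, 2694 and 580 counts. Its level was 1.78 ± 0.43 (SE) above the median gene and was not called above the 2-fold band (limma adjusted p = 0.11), and without replicate 3 it was, at 2.52 (limma adjusted p = 4.7e-06). It was also called above without a filter on low values, which lowers the median gene (3.14, limma adjusted p = 0.00018). The gene (ENSMUSG00000048806.4) lies on chromosome 4 at 88522025 to 88522774. The other 16 members, mostly interferon alpha genes, lay under 1 TPM, with Ifna2 at 0.127 ± 0.126 TPM, and Ifna4 and Ifna1 at 0.0333 ± 0.0306 and 0.0267 ± 0.0306 TPM. The interferon alpha genes are close copies of each other, so their values are uncertain.

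Interferon-stimulated genes were well represented at 60 min. Rsad2 (viperin) was highest at 138 ± 59.3 TPM, followed by Bst2 (tetherin, 121 ± 57.2), Ifi204 (91.9 ± 23.3) and Ifit2 (87.0 ± 43.8 TPM). Among 30 tested members 20 were above the median gene, 10 were not called and 0 were below, and the list's median was 26.5 ± 10.6 TPM (percentile 100). Over all members, the median cytokine gene exceeded the median interferon-stimulated gene by 0.36, 0.45 and 0.68 on the log2(TPM + 0.1) scale in replicates 1, 2 and 3, a mean of 0.50 ± 0.16. The exact sign-flip permutation test gave a 2-sided p of 0.25, the smallest possible with 3 libraries.

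Genes usually linked to later inflammation were mixed. Acod1, which encodes the itaconate-producing enzyme, stood at 90.8 ± 55.5 TPM, Ptgs2 (cyclooxygenase 2) at 52.2 ± 13.2, Cd40 at 28.9 ± 17.4 and Saa3 (serum amyloid A3) at 23.8 ± 18.0 TPM. Of the 14 tested members 3 were above the median gene, 4 below and 7 were not called, and the list's median was 9.44 ± 2.84 TPM. The 5 members under 1 TPM were Nos2, Fpr1, Fpr2, Ptges and Mmp9, with Nos2, the inducible nitric oxide synthase gene, at 0.0767 ± 0.00577 TPM. Saa3 was not called over all libraries (1.45 ± 0.44, limma adjusted p = 0.32) and was called above without replicate 1 (2.09, limma adjusted p = 0.0030) and without a filter on low values (2.81, limma adjusted p = 0.00054). The mean of Saa3 was 13.7 TPM without replicate 3, and that of Cd40 19.1 TPM without replicate 1. The members under 1 TPM were named after their values were seen.

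In the Toll-like receptor 4 list 8 of 21 members were above, 1 below and 12 were not called, with the co-receptor gene Cd14 at 485 ± 77.3 TPM, Irf5 at 45.6 ± 7.61, Tab2 at 26.3 ± 6.88 and Myd88 at 25.6 ± 7.65 TPM. Of 12 inflammasome genes 5 were above and 2 below, with the sensor gene Nlrp3 at 115 ± 36.8, Casp1 at 28.1 ± 7.11, Casp4 at 23.8 ± 10.3 and Aim2 at 19.6 ± 3.98 TPM. The medians of these lists were 13.6 ± 3.60 and 14.8 ± 5.36 TPM. Of the genes associated with alternative activation, Mrc1 (mannose receptor) and Tgm2 (transglutaminase 2) stood at 105 ± 27.3 and 75.4 ± 23.0 TPM, and Il4ra and Pparg at 18.6 ± 5.88 and 17.4 ± 2.36 TPM. All 4 were above the median gene, Il4ra and Pparg not with kallisto's TPM (limma adjusted p = 0.67 and 1). The other 2 tested members were not called and 7 lay under 1 TPM. Arg1, the arginase 1 gene, had 0, 1 and 1 counts and was named after its values were seen.

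Most marker transcripts of other cell types were scarce, with exceptions among neutrophil, T and NK cell and B cell markers. Whether the exceptions came from macrophages or from other cells was not tested. No erythroid or mast cell marker reached a mean of 1 TPM. Alas2, Klf1, Hba-a2 and Hbb-bs stood between 0 and 0.0200 TPM, and Kit, Gata2, Prg2 and Cpa3 between 0.0333 and 0.567 TPM. Of 13 neutrophil markers 5 exceeded 1 TPM, namely S100a9 (15.9 ± 1.96), Csf3r (13.7 ± 4.21), S100a8 (10.1 ± 1.33), Mmp8 (4.52 ± 1.56) and Ngp (1.92 ± 0.307 TPM), the last below the median gene and the others not called. Among T and NK cell markers, Cd4 was at 18.2 ± 3.79 TPM, with Lck, Cd3d and Nkg7 at or under 0.0433 TPM. Cd4 and Blnk were above the median gene, Cd4 though not with kallisto's TPM (limma adjusted p = 0.94). Among B cell markers, the adaptor gene Blnk was at 45.2 ± 12.9 TPM, Ighm at 3.21 ± 0.990, Cd79b at 0.480 ± 0.151 and Igkc at 0.237 ± 0.0723 TPM. Batf3 (1.25 ± 0.336 TPM) was the highest dendritic cell marker, ahead of Kmo, Siglech and Ccr9, which were under 1 TPM. Both Batf3 and the endothelial gene Kdr were below the median gene. Kdr (2.28 ± 1.05 TPM) was the highest stromal or endothelial marker, ahead of Pecam1, Cdh5 and Col1a2 at 0.177, 0.123 and 0.0367 TPM. Without a filter on low values, which lowers the median gene, S100a9, Csf3r and S100a8 were called above it and Ngp, Batf3 and Kdr were no longer called below it. The 24 macrophage markers exceeded the 71 pooled markers of other cell types by 10.34 ± 0.42 on the log2(TPM + 0.1) scale, in 3 of 3 libraries (exact sign-flip permutation test, 2-sided p = 0.25, the smallest possible). The size of this difference depends on the pseudocount, since most of the 71 genes were near 0, and was 7.30 with a pseudocount of 1.

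Short noncoding RNAs took a large part of the TPM. The 2 copies of 7SL, the RNA of the signal recognition particle (Rn7s1 and Rn7s2), stood at 313635 ± 30882 and 316436 ± 31955 TPM. They share their sequence, so the split between them is uncertain. Together they took 57.2, 69.6 and 62.2% of the TPM but 8.08, 14.4 and 10.5% of the expected counts in replicates 1, 2 and 3. Counting error on these count shares was small, with a 95% Wilson interval of 8.07 to 8.09% in replicate 1. Next came 7SK (Rn7sk, a regulator of transcription elongation) at 44482 ± 15043 TPM, Rpph1 (the RNA of RNase P) at 32077 ± 8566 TPM and Rmrp (the RNA of RNase MRP) at 9978 ± 4924 TPM, the last annotated as a pair of overlapping genes whose reads may be split, so that its value is uncertain. Nuclear-encoded protein-coding genes took 32.7, 21.6 and 23.6% of the TPM and 88.8, 82.4 and 85.4% of the counts, and 11.4, 10.9 and 12.2% of kallisto's TPM. The SD of each TPM value from the gene tables therefore includes this difference in composition. Levels in TPM depend on the quantifier and the scaling, with Tnf at 673 TPM and Junb at 187 TPM in kallisto's table, and at 6178 and 1712 when TPM was rescaled over protein-coding genes.

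RNAs that are usually kept in the nucleus were detected in the cytosolic fraction. Beside 7SK, Malat1 stood at 417, 122 and 323 TPM, Neat1 at 38.9, 12.4 and 35.9 TPM, and Xist, the RNA that coats the inactive X chromosome, at 8.81, 0.760 and 2.85 TPM in replicates 1, 2 and 3. Replicate 2 was lowest in 6 of the 7 nuclear-retained RNAs with enough counts to compare. Over all members, most of them low, the median ribosomal protein gene exceeded the median nuclear-retained RNA by 8.12 ± 0.59 on the log2(TPM + 0.1) scale (higher in 3 of 3 libraries, exact sign-flip permutation test, 2-sided p = 0.25, the smallest possible). Of the 10 nuclear-retained RNAs 5 had a mean of at least 1 TPM, with a median of 29.1 ± 14.5 TPM. The 9 RNAs of the list named cytoplasmic noncoding RNAs, which includes the mainly nuclear or nucleolar Rpph1 and Rmrp, were all above 1 TPM, with a median of 187 ± 44.2 TPM. Neither list was tested with limma, since the test covered protein-coding genes.

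Most ribosomal protein, mitochondrially encoded, glycolysis and housekeeping genes were above the median gene. All 76 tested ribosomal protein genes were above the median gene, with Rpl41, Rps29, Rplp1 and Rps28 at 890 ± 84.9, 850 ± 215, 729 ± 205 and 611 ± 119 TPM and a list median of 240 ± 59.7 TPM. Of 13 mitochondrial messages 12 were above, led by mt-Atp8 (1284 ± 215), mt-Co1 (842 ± 197), mt-Nd1 (300.2 ± 55.4) and mt-Cytb (291 ± 65.2 TPM). The order of the first 2 depends on the quantifier, with mt-Atp8 at 311 and mt-Co1 at 374 in kallisto's TPM. Mitochondrial messages took 0.456, 0.426 and 0.450% of the expected counts in replicates 1, 2 and 3. Of 17 glycolysis genes 11 were above and 1 below, with Gapdh at 302 ± 20.6, Aldoa at 155 ± 30.0, Pkm at 111 ± 22.1 and Ldha at 98.7 ± 19.0 TPM. Of 15 housekeeping genes 13 were above and 1 below, led by Actb, B2m (1727 ± 557), Eef1a1 (1727 ± 324) and Ppia (432 ± 98.9 TPM).

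More proliferation genes lay below the median gene than above it. Of 17 tested cell cycle genes 9 were below the median gene, 6 were not called and 2 were above, the clamp gene Pcna (71.5 ± 13.1 TPM) and Mki67 (18.7 ± 6.81 TPM). Mki67 was above by 1.32 ± 0.08 (limma adjusted p = 0.0069), but not without replicate 1 (1.17, limma adjusted p = 0.067) and not with kallisto's TPM (0.88, limma adjusted p = 1). Mcm6 (8.27 ± 2.67) and Cdk1 (6.73 ± 2.75 TPM) were not called, though Mcm6 was called above without a filter on low values (limma adjusted p = 0.0019). The list's median was 2.41 ± 1.24 TPM, at percentile 0.11. That percentile was 7.02 with kallisto's TPM, 4.68 with TPM rescaled over protein-coding genes, 14.9 with kallisto's TPM rescaled in that way (chosen after the data were seen) and 3.66 with a minimum mean of 5 TPM. Of 53 tested replication-dependent histone genes 3 were above and 10 below, with Hist2h2aa2, Hist1h1c, Hist1h2bc and Hist1h4h at 49.8 ± 19.6, 45.4 ± 14.6, 36.6 ± 7.84 and 19.4 ± 9.31 TPM. Hist1h4h was not called (1.34, limma adjusted p = 0.22) and was called above without replicate 1 (1.65, limma adjusted p = 0.014) or without a filter on low values (2.70, limma adjusted p = 1.7e-05). The histone list's median was 3.68, 3.15 and 10.29 TPM in replicates 1, 2 and 3, a mean of 5.71 ± 3.98 TPM at percentile 17.1. That percentile was 51.8 without replicate 1 and 0.04 without replicate 3. It ranged from 0.03 with a minimum mean of 5 TPM, through 6.08 with kallisto's TPM and 49.3 with rescaled TPM, to 75.1 with kallisto's rescaled TPM. Histone genes include near-identical copies, so the values of single members are uncertain. Adjusted over the list alone, the counts equalled those over all genes in every list except 3, namely 4 cytokine genes below, 21 interferon-stimulated genes above and 8 histone genes below.

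Cytokine, interferon-stimulated and cell cycle genes, like several other lists, varied more between libraries than random lists of like abundance. Of the genes with enough counts, 28 of 29 cytokine and 29 of 31 interferon-stimulated genes were lowest in replicate 3, where 18 of 19 cell cycle genes were highest, a comparison made after the data were seen. Across 21359 genes, Pearson's r of log2(TPM + 0.1) was 0.985, 0.985 and 0.990 for replicates 1 and 2, 1 and 3, and 2 and 3, and Spearman's rho 0.948, 0.9496 and 0.958. Genes are not independent replicates, so no p is given. Each pair differed beyond counting error in 5659 to 6101 of 13026 genes, so no pair matched within sampling noise as copies of a library would, and 8136 genes differed over all 3 (chi-square tests, Benjamini-Hochberg adjusted). The median tagwise biological coefficient of variation (BCV) from edgeR was 0.122. Cytokines and chemokines had a median BCV of 0.204 (percentile 100 among 10000 lists of like abundance), late inflammatory genes 0.266 (100), interferon-stimulated genes 0.141 (100), cell cycle genes 0.295 (100), histones 0.400 (100) and nuclear-retained RNAs 0.320 (100). Regulators of mRNA decay (0.0909, percentile 1.13) and glycolysis genes (0.0959, percentile 4.0) had low percentiles. Without replicates 1, 2 and 3 in turn these were 15.4, 7.88 and 1.56 for mRNA decay and 9.38, 3.27 and 42.5 for glycolysis. High percentiles were not special to response genes, since 15 of 28 lists lay in the top 2.5% of random lists, among them ribosomal protein genes (0.123, percentile 100) and housekeeping genes (0.125, percentile 98.1). Housekeeping genes lay below that level at 94.7, 90.7 and 97.2 without replicates 1, 2 and 3, at 96.6 without a filter on low counts and at 77.9 with DESeq2's gene-wise dispersions, and ribosomal protein genes at 97.1 without replicate 3. Without replicate 3 that number fell to 9, of which 7 were shared, and the cell cycle list moved from percentile 100 to 23.6, the NF-kB subunit list from 99.2 to 6.73 and the immediate early list from 99.99 to 87.1.

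The genes of at least 10 TPM with the highest BCV were mostly noncoding or overlapped other genes. Gm49369 (27.5, 597 and 643 TPM in replicates 1, 2 and 3, BCV 0.852) overlaps Ctsd on the same strand over 6757 bases of chromosome 7, and its mean of 423 TPM was 18.3 with kallisto, so its value is uncertain. Gm20721 (0.95, 23.3 and 14.4 TPM) overlaps Gnas on the other strand over 16394 bases, and its mean of 12.9 TPM was 0.241 with kallisto, under the minimum of 10 TPM, so its value is uncertain too. The snRNA genes Gm23444 and Gm23472 had the same 506, 9.68 and 429 TPM, and Gm26316 had 56.0, 3.46 and 7.77 TPM. The first 2 also had the same fractional counts (958.22, 30.25 and 920.74), so they may share 1 set of reads and are not separate evidence. Gm26917, a long intergenic RNA on chromosome 17 at 39843013 to 39846341, stood at 336, 13.8 and 28.6 TPM, and whether it collects reads of ribosomal RNA was not tested. The pseudogene Gm49037, inside Mapk8, had 2.67, 17.8 and 19.9 TPM, and Snord17, inside Snx5, had 23.2, 2.15 and 5.26 TPM. With kallisto the means of Gm26316, Gm49037 and Snord17 were under 10 TPM as well, at 4.59, 2.18 and 3.42 TPM.

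**Figure D3:**
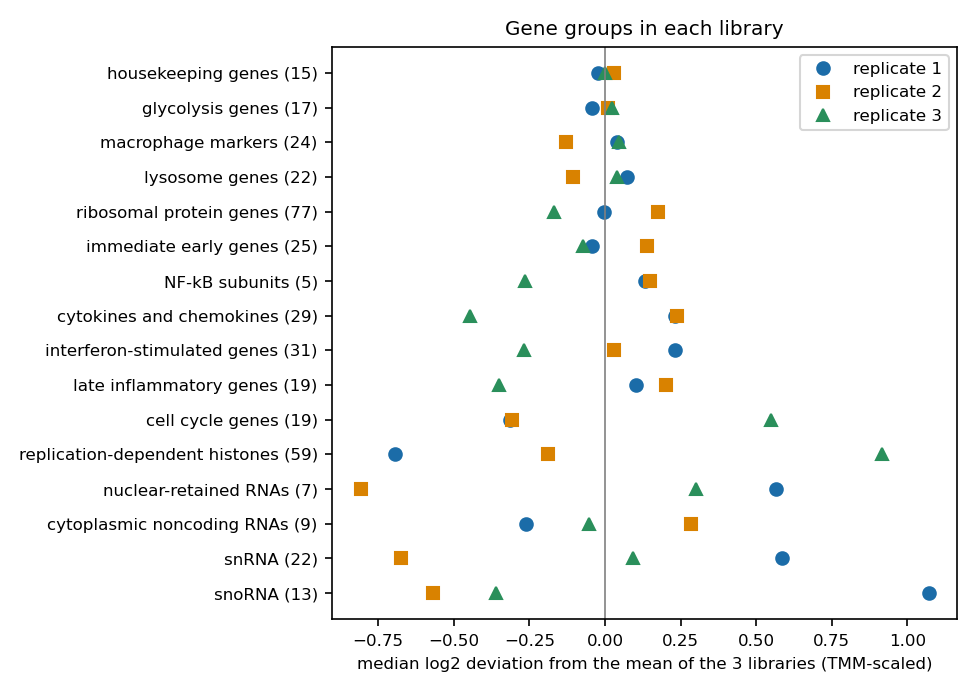
Median log2 deviation of each gene group from the mean of the 3 libraries (TMM-scaled counts) in replicates 1, 2 and 3, with the number of genes in brackets. Housekeeping genes lie near 0 in each library, while the cytokine median lies at -0.45 and the cell cycle median at 0.55 in replicate 3, and the nuclear-retained median at -0.81 in replicate 2.

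The leading isoform of most genes was the same in all libraries. Among 8626 genes with a mean of at least 1 TPM and at least 2 annotated transcripts, 7913 (91.7%) had the same most abundant transcript in the 3 libraries, and pairs of libraries shared 93.7, 94.2 and 95.2%. In 96.5% of the 7779 protein-coding genes among them that transcript was itself annotated as protein-coding, and in 1.13% it was annotated as a retained intron.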

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

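The tests on library scaling, on dilution by other cells and on 7SK were chosen only after the results were seen, as was the calculation of each group's deviation per library, while those on length and GC content and on retained introns were set before their results were seen. The SEs of gaps between lists come from a bootstrap of the listed genes within a library. They show spread among genes, which are not independent replicates, and not spread between cultures. Control sequence outside the annotated genes gave counts above what a count of 0 allows. The phiX genome, a sequencing control, held 166626, 67252 and 40044 counts in replicates 1, 2 and 3. In kallisto's table, ERCC spike-in sequences held 5 counts in replicate 2 and 7 in replicate 3, against 0 in the gene table.

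Replicate 3 stood apart in its cytokine and cell cycle genes. Deviations are relative to the mean of the 3 libraries on the TMM-scaled log2 scale. The median interferon-stimulated gene lay at 0.23, 0.028 and -0.27 in replicates 1, 2 and 3. Of these genes 24 of 31 were highest in replicate 1 and 29 of 31 lowest in replicate 3. In replicate 3 the median cytokine gene fell by 0.45, with 28 of 29 genes lowest there. The median cell cycle gene lay 0.55 higher in replicate 3, with 18 of 19 genes highest there. The cell cycle median lay 0.99 above the cytokine median within that library (bootstrap SE 0.16). A scaling factor, whether from library size or from a few dominant genes, shifts all genes of a library alike and leaves no such gap, so these values argue against it. Lists matched on length and GC content did not reach either deviation (percentile 0 for length or GC content, cytokines, and 100 for cell cycle genes). The bins were coarse and abundance was not matched, so an effect of length within a bin is not excluded. The cytokine median lay at -0.49 (SE 0.11) relative to that of macrophage markers, which dilution by other cells would lower as well. A difference between the cultures in their response or growth stays open; the design has 1 group, and no biological explanation was tested.

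RNAs usually kept in the nucleus were lowest in replicate 2. The median of 7 nuclear-retained RNAs fell by 0.81 there, with 6 of 7 lowest in that library. That of 22 snRNAs, some of which may share reads, fell by 0.68. The nuclear-retained median lay at -0.81 (bootstrap SE 0.26) relative to that of protein-coding genes, a gap that a scaling factor cannot make. Lists matched on length and GC content did not reach the fall of the nuclear-retained list (percentile 0 for gene length or GC content). Matching used coarse bins, so RNAs far longer than most of their bin were not matched closely. Length as a cause is therefore not excluded. Among 1113 protein-coding genes of at least 10 TPM with a mean share of retained-intron transcripts of 1 to 50%, that share was lowest in replicate 2 in 60.5% and highest in replicate 1 in 59.7%, consistent with different amounts of nuclear RNA carried into the fraction. 7SK lay at 0.048 in replicate 2 relative to the protein-coding median, so it did not fall there as this explanation predicts. The short 7SL copies Rn7s1 and Rn7s2 were both raised there, at 0.50. The snRNA median lay at -0.68 and that of 13 snoRNAs at -0.57, so short RNAs did not all move alike. Whether protein-coding genes are a poor baseline for 7SK was not tested. The 7SK value goes against this explanation but does not decide the question on its own. Of the mainly nuclear Rpph1 and Rmrp, Rpph1 was lowest in replicate 1 (0.408, 0.730 and 0.828% of counts). Rmrp differed little between replicates 1 and 2 (0.142, 0.139 and 0.243%). The order of 7SK depends on the scaling, since it was lowest in replicate 1 on the TMM scale and lowest in replicate 2 in TPM (36384, 35222 and 61838). No biological explanation was tested.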

How the results depend on the processing

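Rescaling kallisto's TPM over protein-coding genes was chosen after the data were seen and gave 13210 expressed genes. No paired analysis was possible because the labels give 1 group. The 4 differences between lists kept their sign under each alternative run. With a minimum mean of 5 TPM, 5850 genes were expressed and 92.9% of genes kept the same leading isoform. With a pseudocount of 1, the mean Pearson r was 0.991 (0.987 as reported), and the differences fell to 7.30 for macrophage markers minus other cell types and 7.02 for ribosomal protein genes minus nuclear-retained RNAs. With FPKM the first was 10.97, and with kallisto the 2 were 9.16 and 7.26. With kallisto 1427 genes lay below the typical gene and the median BCV was 0.144. Without a filter on low values 4986 genes lay above and 5463 below among 14388 genes, since low genes are then tested too and lower the median gene, and without a filter on low counts the median BCV was 0.285. The gene-wise dispersions of DESeq2, which are not shrunk, gave 0.0688. Apart from the filters, the cause was not tested. Leaving out each library in turn left the pairwise Pearson r of 0.985 to 0.990 already given. It also gave a median BCV of 0.120 to 0.135. The share of genes with the same leading isoform was then 93.6 to 95.3%, which rises because fewer libraries must agree. From 9 to 15 lists lay in the top 2.5% for variability, the 9 without replicate 3. Of the named genes tested with limma, the calls that changed were those of Ifnb1, Saa3, Mki67 and Hist1h4h without 1 library, 4 with kallisto and 10 without a filter on low values. Named genes' TPM moved by more than 1 SD with kallisto in 114 of 137 cases and with rescaled TPM, by construction, in 136 (Tnf 673 and 6178 against 1641 TPM). Low counts limit the interferon alpha genes and most markers of other cell types.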

Other observations

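The deviations of gene groups per library were computed only after the data were seen. Replication-dependent histone messages, which lack poly(A) tails and are made in S phase, differed between libraries, with medians of -0.69, -0.19 and 0.92 on the log2 scale in replicates 1, 2 and 3, and 54 of 59 genes were highest in replicate 3. Ribosomal protein genes moved differently, at -0.0030, 0.17 and -0.17, with 68 of 77 genes lowest in replicate 3. Immediate early genes lay at -0.044, 0.14 and -0.073, and late inflammatory genes at 0.10, 0.20 and -0.35. Cxcl10 had 23886, 27317 and 5777 counts, Il12b 4787, 3367 and 580, and Saa3, which went the other way, 329, 936 and 1917. These genes were chosen after their values were seen.

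Xist was counted in each library (13071, 1367 and 5017 counts), while the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had 0 counts in the gene tables. In kallisto's table Kdm5d had 45.8, 14.5 and 31.2 counts and Uty 12.6, 7.15 and 12.8, with at most 8 for the other 2. The sex of the mice is given in the labels as not collected.

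In kallisto's table the pseudogenes Gm12895 and Gm12896 took 32.2, 25.4 and 21.3% of the TPM, and the annotated microRNA genes Gm24245, Gm24270 and Gm23935 took 34.3, 30.4 and 35.5%, while all 5 had 0 counts in the gene tables. Whether these features collect reads of ribosomal RNA was not tested, so the shares are those of the features as annotated. The 7SL copies took 18.4, 29.3 and 25.0% of kallisto's TPM.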
